A study of Mus musculus with 4 samples.

How the data were processed

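Cells of the lateral wall of the subventricular zone of mice at postnatal day 14 were profiled by 3' single-cell RNA sequencing (PIPseq T20 kit, 40000 cells per reaction per the labels) in 4 libraries, 2 of WT and 2 of NDUFS4 KO mice. WT replicate 1 pooled male and female tissue and the other libraries were female. The authors aligned reads with STAR to GRCm39 and counted them with PIPseeker, per the submitters' processing notes, whose versions are not given in the sources used here, nor is the gene annotation. The deposited matrices hold counts, whole numbers per gene and barcode, for 32227 genes and all barcodes, and the labels do not say whether molecular identifiers were used to remove duplicates. Of the gene symbols 54 belong to several gene identifiers and were kept apart by identifier. The reference tables at hand use another genome build, so no coordinates were used, and gene lengths alone were taken from them.

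The libraries held 105507992 counts (WT replicate 1), 103113033 (WT replicate 2), 107753120 (KO replicate 1) and 60181767 (KO replicate 2) in 3041862, 2613376, 2622914 and 2074885 barcodes. A barcode was kept as a cell with at least 300 genes and a count of at least the larger of 500 and the count at the steepest descent of its library's smoothed curve of log count against log rank (ranks 2000 to 60000, a window of 41 of 200 points). These minima came to 941, 544, 1200 and 1434 counts. Cells with over 20% mitochondrial counts were removed. Doublets were called by Scrublet in scanpy 1.11.5 per library, and where its own threshold called under 0.5% or over 20% of cells, as in WT replicate 2 (0.037%) and KO replicate 2 (0.133%), the 5% of highest score were removed. Barcodes over the count minimum held 47.0%, 49.9%, 52.7% and 24.9% of the counts of the 4 libraries, and 46312 cells were kept in all.

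Cells were clustered together with scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2 and igraph 0.11.9 under Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0, and figures were drawn with matplotlib 3.10.9. The 2000 most variable genes were chosen within libraries, log values were centred on each library's mean, and 30 principal components, 15 neighbours and Leiden resolution 1 were used. Of the 31 clusters 28 took the name of the best of 17 marker lists. A marker's log2 fold over other cells (10 CPM added) counted if it was detected in at least 10% of the cluster's cells, and a name needed a mean of at least 0.5, at least 3 markers at 1 or more and at least 30 cells. No other class could hold more markers among the top 10 genes, and clusters with under 0.333 of the median count and no own marker among the top 10 stayed unnamed.

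Counts were summed per library and class, for the 10 classes with at least 50 cells in every library, and tested between genotypes with edgeR 4.0.16 (filterByExpr by group, TMM, glmQLFit, glmQLFTest, Benjamini-Hochberg adjustment, threshold 0.05) under R 4.3.3. Fold changes are KO over WT on the log2 scale with their SE, and n counts libraries. Class shares were tested with the same quasi-likelihood test on cell counts of 16 classes, and by exact permutation, whose smallest two-sided p with 2 against 2 libraries is 0.333. The 28 gene lists of the report were tested with camera (correlation 0.01, then an estimated correlation) and fry of limma 3.58.1, for lists of at least 5 measured genes, adjusted over lists within a class. Genes were named by rule: the 10 highest and 10 lowest fold changes among genes with an adjusted p under 0.05, a mean of at least 20 CPM and both KO libraries on the same side of both WT libraries. Where none passed, the 5 of smallest p in each direction under the same rule were named. Ndufs4 and up to 4 members of smallest p per gene list were added, some of which are not reported, and haemoglobin, predicted and sex-linked genes were left out of the rule. This left out 1 called gene in progenitors, 5 in mural cells and 9 in oligodendrocytes. Marker lists, gene lists, the naming rule, tests and most alternatives were chosen before the data were examined. For the other classes, Ndufs4 and up to 5 genes of smallest adjusted p in each direction were named under the same rule.

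The share of background was estimated per class and library as the median, over markers of unrelated cell types of at least 50 CPM in background, of their fraction in the class over their fraction in barcodes of 50 to 150 counts. The 4 libraries held 281606, 253698, 308459 and 107838 such barcodes. Subtraction of that share and a separate clustering of each library were alternatives chosen after seeing the data. So was the count range, first set at 5 to 50.

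Summed counts were 3587190, 5456021, 5525676 and 851121 for neuroblasts, 5164405, 4128615, 4648138 and 1861290 for progenitors and 7634643, 12241434, 11672856 and 2113033 for stem cells or astrocytes, in the order above. The biological coefficient of variation was 0.262, 0.268 and 0.278 in these classes. Tested on simulated data with 200 changed genes, 5 times per class, edgeR recovered 14.6%, 16.0% and 11.4% of genes changed 2-fold and 88.6%, 91.8% and 85.0% of those changed 4-fold, with 6.4, 6.4 and 12.6 false calls on average. Without any change it made 4, 2 and 4 calls. Lists shifted by 0.6 were called by camera (unadjusted p under 0.05) in 5 of 5 simulations of each class, and unshifted lists in 0, 2 and 0. The simulated genes varied independently of each other, whereas the estimated correlation of ribosomal protein genes in neuroblasts was 0.88. These simulations therefore do not show how often camera calls a list of correlated genes without a change. A 4-fold change of a class share was called in 12% of simulations at the spread of these data.

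Alternatives were DESeq2 1.42.0 (its Wald test, and its size factors in edgeR), other filters on low counts, each library left out in turn, the replicate number as a block, cells thinned to 1000 counts, doublets kept, other mitochondrial limits and count minima, and other cluster settings. Where a library was left out, the lone library of its group was assumed to vary like the other group. Intervals on shares of single libraries cover counting error only.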

Results

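Single-cell transcriptomes were collected from the subventricular zone, the neurogenic niche along the lateral ventricle, of mice at postnatal day 14. The 4 libraries were 2 biological replicates of wild-type (WT) mice and 2 of mice lacking NDUFS4, an accessory subunit of respiratory complex I whose loss is used as a mouse model of Leigh syndrome. The comparison of genotypes asked, per the series title, how complex I deficiency affects postnatal neurogenesis. WT replicate 1 held 105507992 counts, WT replicate 2 held 103113033, KO replicate 1 held 107753120 and KO replicate 2 held 60181767. After filtering, 12634 and 17774 cells were kept from the WT libraries, and 12328 and 3576 from the KO libraries. Median counts per cell were 2517 and 1595 in WT, and 3386 and 2966.5 in KO. WT replicate 1 pooled both sexes and the other libraries were female, per the labels. The library names of WT replicate 2 and KO replicate 1 carry the same date, and each value of that pair is given below as the same-date value, without a test because it holds 1 library per genotype. In neuroblasts and progenitors WT replicate 2 held the highest share of background counts (51.9% and 53.03%) and KO replicate 1 the lowest (16.0% and 13.2%). Same-date values carry that difference.

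Ndufs4 (ENSMUSG00000021764) transcripts were present in every library. Over all kept cells the level was 188.7 and 150.9 counts per 1e6 counts after TMM scaling (CPM, scaled so throughout) in the WT libraries, and 118.3 and 170.6 CPM in the KO libraries. The group means were 169.8 ± 26.7 CPM in WT and 144.4 ± 37.0 CPM in KO (SD, n = 2 each), a log2 fold change of -0.23 ± 0.38 (SE; edgeR adjusted p = 0.953). Without TMM scaling the libraries did not overlap, at 188.8 and 172.5 per 1e6 counts in WT against 117.5 and 149.9 in KO, and the log2 fold change was -0.435 ± 0.36 (adjusted p = 0.935). Within the 3 neurogenic classes the log2 fold change of Ndufs4 was -0.18 ± 0.36 in neuroblasts, -0.29 ± 0.37 in proliferating progenitors and -0.22 ± 0.35 in stem cells or astrocytes (edgeR adjusted p = 0.923, 0.766 and 0.863). Same-date values were -0.14, -0.28 and -0.30. In ependymal cells and microglia, Ndufs4 lay lower in each KO library than in each WT library, with log2 fold changes of -0.63 ± 0.32 and -0.52 ± 0.33 (edgeR adjusted p = 0.715 and 0.617), and same-date values of -0.62 and -0.66. Over all cells, leaving out KO replicate 1 turned the Ndufs4 log2 fold change to 0.007, and leaving out KO replicate 2 gave -0.53. The 3' tags counted here may lie outside the deleted part of the gene, so the Ndufs4 level checks neither the knockout nor the labels.

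**Figure D1:**
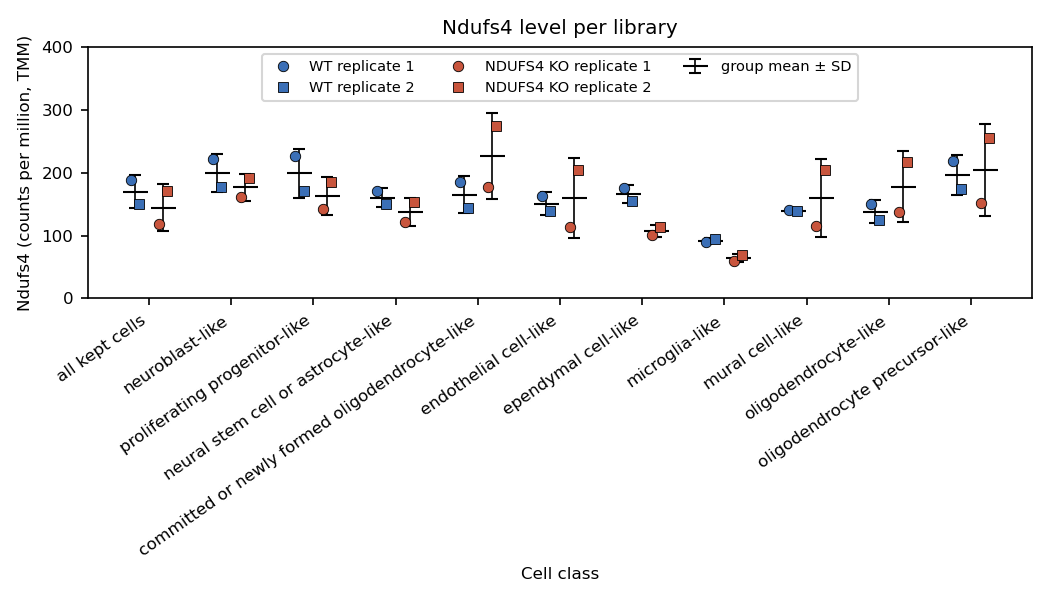
Ndufs4 level in CPM for each library, in all kept cells and in each of the 10 tested classes, with points for libraries and bars for group means and SD. KO libraries lay below WT libraries in ependymal cells and microglia and overlapped with them over all kept cells, where the means were 169.8 and 144.4 after TMM scaling. Without that scaling both KO libraries lay below both WT libraries over all kept cells.

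Cells fell into 31 clusters, 28 of which took a name from fixed marker genes, and each name means cells resembling that type. Neuroblasts, the migrating young neurons marked by Dcx and Dlx genes, made up 13.1% and 18.9% of WT cells and 15.7% and 8.50% of KO cells. Their mean share was 16.0% ± 4.05 in WT and 12.1% ± 5.06 in KO (SD, n = 2 each). The log2 fold change was -0.41 ± 0.51 (SE) and did not pass the edgeR test (adjusted p = 0.949), with a same-date value of -0.27. Proliferating progenitors made up 8.99% ± 4.25 of WT cells and 9.58% ± 3.06 of KO cells (log2 fold change 0.09 ± 0.61, same-date value 0.31). Stem cells or astrocytes, which share most markers and were kept as 1 class, made up 24.9% ± 5.68 and 22.8% ± 4.90 (log2 fold change -0.13 ± 0.37, same-date value -0.14). The edgeR adjusted p was 0.949 for each of these classes. Of the neurogenic lineage formed by the 3 classes, neuroblasts held 31.9% ± 4.62 in WT and 26.6% ± 7.25 in KO (log2 fold change -0.26 ± 0.52, edgeR adjusted p = 0.808), with a same-date value of -0.15.

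Among the other classes, endothelial cells were 4.32% and 4.51% of WT cells and 7.50% and 9.59% of KO cells. The log2 fold change was 0.95 ± 0.63 (SE, edgeR adjusted p = 0.694; two-sided exact permutation p = 0.333, the smallest that 2 against 2 libraries allow). Microglia made up 19.4% and 7.07% of WT cells, against 17.3% and 16.4% of KO cells. Choroid plexus epithelium held 5.50% of cells in WT replicate 1 and 0.169% in WT replicate 2, against 0% in KO replicate 1 and 0.168% in KO replicate 2. None of the 16 classes passed the edgeR test of shares, in which the lowest adjusted p was 0.151, for erythrocytes. Clusters without a name held 0.989% and 12.1% of cells in the WT libraries, and 0.698% and 2.13% in the KO libraries. Different clusters held the same class: 98.3% of neuroblasts of WT replicate 2 lay in 1 cluster of their own, while 75.6%, 84.9% and 90.8% of neuroblasts of WT replicate 1, KO replicate 1 and KO replicate 2 lay in another. Among stem cells or astrocytes the largest cluster of WT replicate 2 (40.1% of its cells) was likewise not the one that led in WT replicate 1, KO replicate 1 and KO replicate 2 (43.2%, 46.3% and 72.2%). Of proliferating progenitors 98.8% lay in 1 cluster in WT replicate 2, which held 51.9%, 58.3% and 51.4% in WT replicate 1, KO replicate 1 and KO replicate 2. The other cluster, led by genes such as Ung, Gins2 and Hes5, held 13 progenitors of WT replicate 2, against 729, 382 and 204 in WT replicate 1, KO replicate 1 and KO replicate 2. Of microglia 89.6% in KO replicate 2 lay in a cluster other than the one that held 89.9%, 70.5% and 94.3% in WT replicate 1, WT replicate 2 and KO replicate 1. The direction of the progenitor share turned without WT replicate 2 (-0.33) and without KO replicate 2 (-0.28), and that of the stem cell or astrocyte share turned without the same libraries (0.13 and 0.08).

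**Figure D2:**
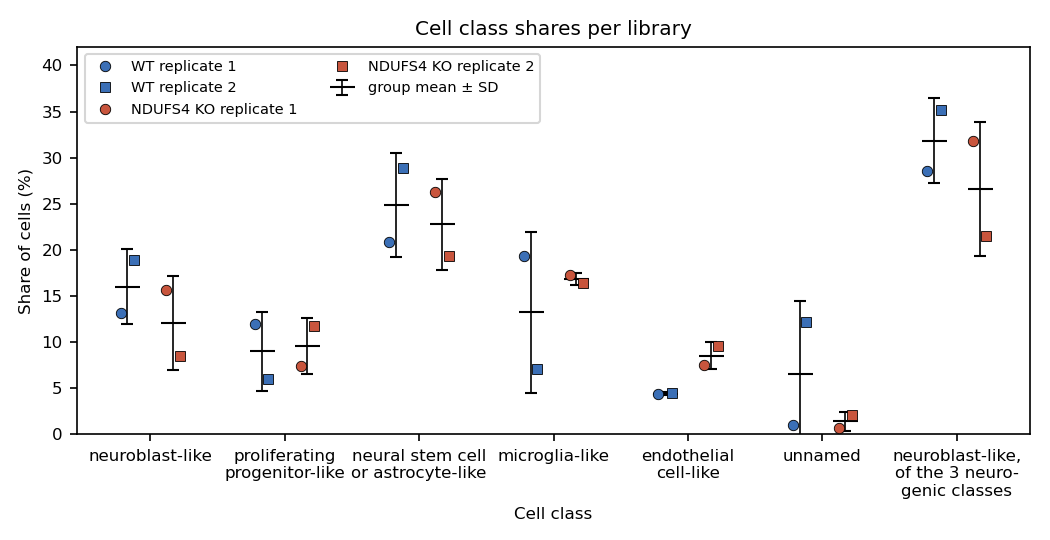
Share of kept cells per library, in percent, of the 3 neurogenic classes, microglia, endothelial cells and unnamed cells, and of neuroblasts within the 3 neurogenic classes, with points for libraries and bars for group means and SD. Neuroblasts averaged 16.0% in WT and 12.1% in KO, and endothelial cells lay at 4.32% and 4.51% in WT against 7.50% and 9.59% in KO.

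The share of background counts was lower in both KO libraries than in both WT libraries, and KO replicate 2 differed from the other libraries in composition. Counts matching the profile of cell-free barcodes made up 31.1% and 51.9% of neuroblast counts in WT but 16.0% and 18.1% in KO, estimated from markers of unrelated cell types. In proliferating progenitors that share was 29.6% and 53.03% in WT against 13.2% and 15.2% in KO, and in stem cells or astrocytes 32.2% and 52.8% against 15.4% and 17.3%. Ttr, the transthyretin of the choroid plexus, reached 65653 CPM in cell-free barcodes of WT replicate 1, against 427 in WT replicate 2, 1.66 in KO replicate 1 and 474 in KO replicate 2. KO replicate 2 stood apart from the other libraries in its ribosomal protein transcripts, at 17.2% of neuroblast counts against 11.3%, 8.78% and 13.03% in WT replicate 1, WT replicate 2 and KO replicate 1. It also held the lowest level of the nuclear long non-coding RNA Malat1, at 2809 CPM in neuroblasts against 8235, 11400 and 9129.

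In neuroblasts the subunits of the respiratory chain encoded in the nucleus were higher in KO. Of 35 measured complex I subunits other than Ndufs4, 34 were higher, with a median log2 fold change of 0.66 (same-date value 0.28; camera adjusted p = 1.48e-12; adjusted p = 0.799 with an estimated correlation). Of subunits of complexes II to V 37 of 38 were higher, with a median of 0.66 (same-date value 0.37; camera adjusted p = 6.90e-13; adjusted p = 0.799 with an estimated correlation). Examples are the complex I subunit Ndufb5 (1.06 ± 0.43) and Sdhd, a membrane anchor of complex II (1.17 ± 0.38), each with an edgeR adjusted p of 0.734 (SE, n = 2 per genotype). All 39 ribosomal protein genes were higher, with a median of 0.90 (same-date value 0.84; camera adjusted p = 3.88e-25; adjusted p = 0.799 with an estimated correlation), beside the high ribosomal share of KO replicate 2. Of 20 oxidative stress genes 15 were higher, with a median of 0.22 (same-date value 0.09; camera adjusted p = 0.0390; adjusted p = 0.799 with an estimated correlation). Members included Gclm of glutathione synthesis (0.89 ± 0.43) and the mitochondrial peroxiredoxin Prdx3 (0.68 ± 0.34). Without KO replicate 2 the medians of complex I, complexes II to V and ribosomal proteins were 0.26, 0.30 and 0.56, and without KO replicate 1 those of complex I and complexes II to V were 1.05 and 1.07. The oxidative stress call ended without WT replicate 1, WT replicate 2 or KO replicate 2 (camera adjusted p = 0.0588, 0.0887 and 0.311, the last with a median of 0.08), and its median was 0.59 without KO replicate 1.

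In KO neuroblasts 6 lists were lower, and the share of background counts was also lower. All 14 myelin genes were lower, with a median log2 fold change of -0.74 (same-date value -1.38; camera adjusted p = 2.97e-06; adjusted p = 0.799 with an estimated correlation). Named members were Cnp (-1.15 ± 0.37) and Fa2h (-1.37 ± 0.34). Of 18 genes of stem cell quiescence 17 were lower, with a median of -0.46 (same-date value -0.47; camera adjusted p = 0.000389; adjusted p = 0.799 with an estimated correlation). Examples were the astrocyte filament Gfap (-1.49 ± 0.47) and Clu (-0.86 ± 0.38). All 12 homeostatic microglia genes, among them Tmem119 (-0.71 ± 0.35) and Gpr34 (-0.68 ± 0.36), were lower, with a median of -0.51 (same-date value -0.50; camera adjusted p = 0.0412; adjusted p = 0.805 with an estimated correlation). Of 27 G2 and M phase genes 26 were lower, with a median of -0.40 (same-date value -0.73; camera adjusted p = 0.0188; adjusted p = 0.805 with an estimated correlation). Members included the mitotic activator Cdc20 (-1.24 ± 0.48) and the spindle motor Kif11 (-1.21 ± 0.52). Of 18 cholesterol synthesis genes 15 were lower, with a median of -0.37 (same-date value -0.29; camera adjusted p = 0.00632; adjusted p = 0.799 with an estimated correlation). Hmgcs1 stood at -0.85 ± 0.34. Of 28 calcium handling genes 23 were lower, with a median of -0.30 (same-date value -0.23; camera adjusted p = 0.0192; adjusted p = 0.799 with an estimated correlation). Examples were the inositol trisphosphate receptors Itpr2 (-1.18 ± 0.37) and Itpr1 (-0.78 ± 0.34). Each of these members had an edgeR adjusted p of 0.734, except Fa2h with 0.634, which passed when adjusted over the myelin list alone (SE, n = 2 per genotype).

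These calls rested on single libraries in several cases. Without KO replicate 1 the camera calls ended for myelin genes (median -0.18, adjusted p = 0.486), G2 and M phase genes (-0.28, 0.486), homeostatic microglia genes (-0.12, 0.939) and cholesterol synthesis (-0.35, 0.252). The medians of quiescence and calcium handling genes were -0.96 and -0.79 in that case. Without WT replicate 2 the calls ended for G2 and M phase genes (-0.14, 0.935), quiescence genes (-0.24, 0.0839) and calcium handling (-0.27, 0.0904). They ended without WT replicate 1 for cholesterol synthesis (-0.32, 0.1499) and homeostatic microglia genes (-0.09, 0.738), and the quiescence median was -0.72. Without KO replicate 2 calcium handling was no longer called (-0.16, 0.311), and the medians of myelin and homeostatic microglia genes were -1.38 and -0.80. With background subtracted, an alternative chosen after seeing the data, G2 and M phase genes in neuroblasts were called in the opposite direction (median 0.74, 14 higher and 5 lower, camera adjusted p = 0.000577; adjusted p = 0.591 with an estimated correlation). The calls of quiescence (0.19, 0.288), cholesterol synthesis (0.0502, 0.849) and homeostatic microglia genes (-0.73, 0.0887) ended, that of calcium handling stayed (-0.26, 0.0297; adjusted p = 0.591 with an estimated correlation) and myelin genes could not be tested, with under 5 measured.

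No single gene passed in neuroblasts: edgeR called 0 of 14766 tested genes, with 962 at an unadjusted p under 0.05 (423 higher, 539 lower), and DESeq2 called 4, all higher. The 4 were Rps2 (DESeq2 log2 fold change 1.70 ± 0.36, adjusted p = 0.00137), Rpl36 (1.72 ± 0.46, 0.0378), Rpl29 (1.72 ± 0.45, 0.0312) and the ferritin light chain Ftl1 (1.99 ± 0.44, 0.00260). They were named after their values were seen and are uncertain, as genes with many processed copies. The genes of smallest p in edgeR that were higher in each KO library than in each WT library were Zfp14 (2.02 ± 0.43), the general transcription factor subunit Taf9 (1.90 ± 0.41), Rps2 (1.65 ± 0.41), Tex29 (1.45 ± 0.36) and Rnf113a2, an intronless copy of another gene (1.36 ± 0.35). Each had an adjusted p of 0.634 (SE, n = 2 per genotype). Their same-date values ran from 1.39 for Rnf113a2 to 2.69 for Taf9. On the lower side stood Ecrg4 (-4.34 ± 0.86) and the folate receptor Folr1 (-4.07 ± 0.99), both abundant in choroid plexus, the tubulin-binding protein Tppp of oligodendrocytes (-1.97 ± 0.39), the adhesion protein Cntn1 (-1.53 ± 0.35) and the receptor ligand Gas6 (-1.41 ± 0.34). The edgeR adjusted p was 0.622 for Ecrg4 and Tppp and 0.634 for Folr1, Cntn1 and Gas6. Same-date values of these genes ran from -2.24 for Ecrg4 to -1.35 for Folr1. Groups did not overlap for 3188 of 7248 genes of at least 20 CPM (44.0%), where 33.3% is the average over the 3 groupings of the libraries. Genes can move together by library, so a share above that average is not evidence of a genotype effect. Leaving out 1 library at a time gave 24 called genes without WT replicate 1, 40 without WT replicate 2, 799 without KO replicate 1 and 9 without KO replicate 2. Without WT replicate 2 Ecrg4 and Folr1 passed (edgeR adjusted p = 6.01e-10 for each), without KO replicate 1 Zfp14, Rps2 and Rnf113a2 passed (0.0137, 0.0317 and 0.0432), and without KO replicate 2 Taf9 and Tppp passed (0.0451 and 0.0345).

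In proliferating progenitors 8 genes fell in KO. Igfbp2, a binding protein of insulin-like growth factors, fell by 2.93 ± 0.46 on the log2 scale (edgeR adjusted p = 0.0154), from 145.6 and 65.8 CPM in WT to 18.6 and 7.31 CPM in KO. Tppp fell by 2.24 ± 0.39 (adjusted p = 0.0277), and Enpp2, the lysophospholipase autotaxin, fell by 2.89 ± 0.54 (0.0417). Ecrg4 fell by 3.22 ± 0.62 (adjusted p = 0.0474) and the secreted protein Tafa2 fell by 5.05 ± 0.95 (0.0417; SE, n = 2 per genotype). Same-date values were -1.77 for Igfbp2, -2.08 for Tppp, -1.46 for Enpp2, -1.48 for Ecrg4 and -0.50 for Tafa2. The remaining 3 called genes lay outside the naming rule and were named after their values were seen: Sostdc1, Calml4 (fell by 3.78 ± 0.62, adjusted p = 0.0154) and the predicted gene Gm49394 (fell by 2.69 ± 0.44, 0.0154). Sostdc1 (adjusted p = 0.0295) held 67.7 and 2.21 CPM in WT against 0.221 and 0 CPM in KO, so that its fold rests on a few counts. Of the 8 genes 7 were measured in microglia, which should lack them, and were lower there: -3.09 for Igfbp2, -2.91 for Enpp2, -4.33 for Ecrg4, -4.89 for Tafa2, -3.26 for Calml4 and -2.18 for Gm49394, but -0.40 for Tppp. At the level of background counts estimated for each library, 208 and 73.9 CPM of Igfbp2 would stand in WT progenitors and 15.6 and 3.76 CPM in KO progenitors. For Tppp the levels would be 35.6 and 39.4 CPM against 9.88 and 11.1 CPM.

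**Figure D3:**
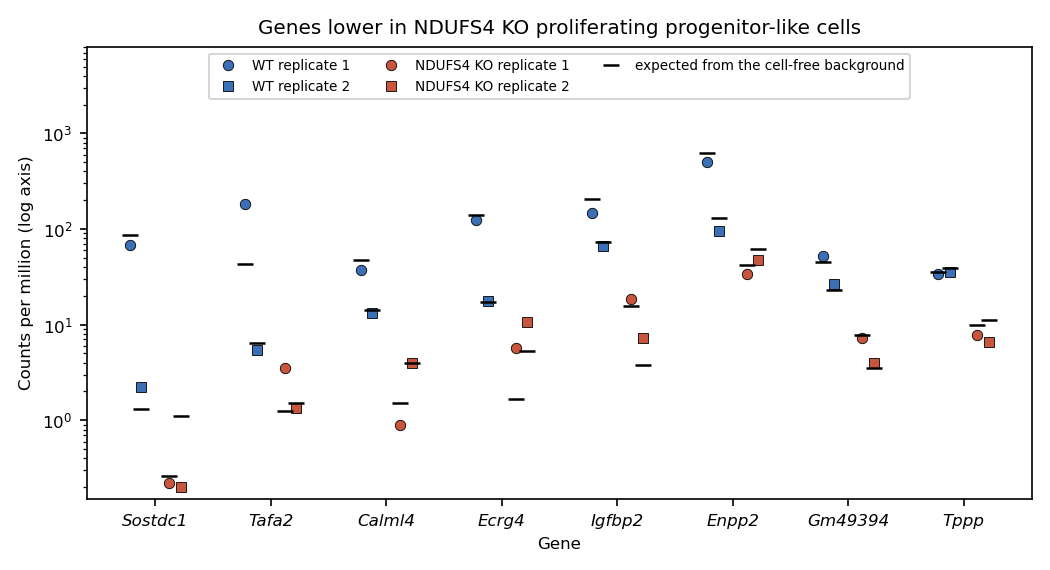
Level in proliferating progenitors, in CPM on a log axis, of the 8 genes that fell in KO, with points for WT and KO libraries and dashes for the level estimated from cell-free background alone. Igfbp2 lay at 145.6 and 65.8 in WT and at 18.6 and 7.31 in KO, and the Sostdc1 value of 0 in KO replicate 2 is drawn at the bottom of the axis.

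The edgeR test called these 8 of 14244 genes, and 1466 genes had an unadjusted p under 0.05 (566 higher, 900 lower). DESeq2 called 8 genes, of which Igfbp2, Tppp, Gm49394 and Calml4 were also called by edgeR. Its other calls were Nfasc, lower (DESeq2 log2 fold change -1.62 ± 0.36, adjusted p = 0.0130) and named after its value was seen, and Rps2 (1.66 ± 0.355, 0.00701), Hes5 (1.47 ± 0.35, 0.0279) and Pin4 (1.96 ± 0.48, 0.0454), higher. In DESeq2 Ecrg4 (-3.07 ± 1.29, adjusted p = 0.438), Enpp2 (-2.82 ± 1.10, 0.438) and Tafa2 (-5.21 ± 1.93, 0.428) did not pass, nor was Sostdc1 called. Among genes that did not pass in edgeR, the isomerase Pin4 (1.90 ± 0.42, adjusted p = 0.0880), the RNA-binding Lsm3 (1.85 ± 0.44, 0.124), Taf9 (1.91 ± 0.52, 0.198), the cell cycle kinase subunit Cks2 (1.51 ± 0.41, 0.203) and Rps2 (1.60 ± 0.44, 0.211) had the smallest p on the higher side. Their same-date values ran from 2.06 for Rps2 to 3.85 for Taf9. Groups did not overlap for 3564 of 6858 genes of at least 20 CPM (52.0%, average over the 3 groupings 33.3%). Without WT replicate 1 or WT replicate 2 edgeR called 0 genes, whereas 617 passed without KO replicate 1 and 184 without KO replicate 2. Without WT replicate 1 the log2 fold changes were -2.23 for Igfbp2 (adjusted p = 0.703), -2.26 for Tppp (0.703), -1.21 for Enpp2 (0.705), -1.17 for Ecrg4 (0.705) and -0.97 for Tafa2 (0.738). Leaving out WT replicate 2 they were -3.41 for Igfbp2 (0.895), -2.19 for Tppp (0.9995), -3.64 for Enpp2 (0.502), -4.01 for Ecrg4 (0.484) and -6.02 for Tafa2 (0.360). Without KO replicate 1 Pin4 and Lsm3 passed (0.00336 and 0.0123), and without KO replicate 2 Pin4, Lsm3, Taf9, Cks2 and Rps2 passed (0.00209, 0.00211, 0.000453, 0.00547 and 0.0477). With DESeq2's size factors in the same edgeR fit 0 genes passed, with -2.89 for Igfbp2 (adjusted p = 0.0943), -2.19 for Tppp (0.0943), -2.83 for Enpp2 (0.181), -3.18 for Ecrg4 (0.181) and -5.02 for Tafa2 (0.181). With background subtracted, an alternative chosen after seeing the data, 2 of the 8 genes were left to test, Ecrg4 at 3.67 ± 1.42 and Gm49394 at -5.11 ± 1.31 (adjusted p = 0.776 each).

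Progenitors shared the higher level of respiratory chain genes. Of 35 complex I subunits 34 were higher, with a median log2 fold change of 0.69 (same-date value 0.44; camera adjusted p = 3.18e-12; adjusted p = 0.635 with an estimated correlation). Members included Ndufs5 (1.18 ± 0.38) and Ndufs3 (0.87 ± 0.37). Subunits of complexes II to V followed with 37 of 38 higher and a median of 0.62 (same-date value 0.50; camera adjusted p = 2.58e-11; adjusted p = 0.635 with an estimated correlation). Named members were Sdhd (0.96 ± 0.38) and Uqcrc1 (0.79 ± 0.37). Complex I assembly factors were higher in 13 of 15 cases, with a median of 0.47 (same-date value 0.37; camera adjusted p = 0.00661; adjusted p = 0.635 with an estimated correlation). Examples were Ndufaf3 (0.79 ± 0.37) and Ndufaf4 (0.66 ± 0.36). Genes of the tricarboxylic acid cycle had a median of 0.18, with 14 of 20 higher (same-date value 0.32; camera adjusted p = 0.0293; adjusted p = 0.672 with an estimated correlation). Idh3g stood at 0.70 ± 0.36. Oxidative stress genes had a median of 0.42, with 15 of 20 higher (same-date value 0.34; camera adjusted p = 0.00661; adjusted p = 0.635 with an estimated correlation), although the cystine transporter Slc7a11 was at -0.94 ± 0.39. All 39 ribosomal protein genes were higher, with a median of 0.76 (same-date value 0.81; camera adjusted p = 5.67e-17; adjusted p = 0.635 with an estimated correlation). None of the members named passed in edgeR (lowest adjusted p = 0.307, for Ndufs5; SE, n = 2 per genotype). Without KO replicate 2 the medians were 0.33 for complex I, 0.31 for complexes II to V and 0.45 for ribosomal proteins, and without WT replicate 2 the ribosomal median was 0.45. The assembly factor call ended without WT replicate 2 (0.39, adjusted p = 0.149) and without KO replicate 2 (0.26, 0.0569), and so did the tricarboxylic acid cycle call (0.01, 0.385, and 0.17, 0.0569). Without KO replicate 1 the medians of complexes II to V, assembly factors and the tricarboxylic acid cycle were 0.96, 0.71 and 0.32, and without WT replicate 1 that of the tricarboxylic acid cycle was 0.44. With background subtracted, an alternative chosen after seeing the data, the calls of assembly factors (0.45, adjusted p = 0.0947) and of the tricarboxylic acid cycle (0.17, 0.192) ended.

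Genes of S phase and of stem cell activation were also higher in KO progenitors. Of 25 S phase genes 24 were higher, with a median log2 fold change of 0.51 (same-date value 0.73; camera adjusted p = 9.12e-05; adjusted p = 0.635 with an estimated correlation). The replication factor Gins2 stood at 0.84 ± 0.37. Genes of G2 and M phase were higher in 17 of 28 cases and not called (median 0.13, camera adjusted p = 0.0868). Activation genes were higher in 12 of 16 cases, with a median of 0.32 (same-date value 0.38; camera adjusted p = 0.0178; adjusted p = 0.635 with an estimated correlation). Of them 2, the Notch target Hes5 (1.41 ± 0.41, edgeR adjusted p = 0.240) and the progenitor transcription factor Gsx2 (1.16 ± 0.37, 0.289), passed when adjusted over the list alone. Immediate early genes, which respond to tissue dissociation, were higher in 16 of 19 cases, with a median of 0.23 (same-date value 0.24; camera adjusted p = 0.0449; adjusted p = 0.635 with an estimated correlation). Examples were Ier2 (1.19 ± 0.36) and Fos (0.88 ± 0.37). Without WT replicate 1 the activation and immediate early calls ended (0.37, adjusted p = 0.0560, and 0.10, 0.291), and they ended as well without KO replicate 1 (0.11, 0.385, and 0.19, 0.399). The S phase median was 0.28 without WT replicate 2 and 0.89 without WT replicate 1. The activation median was 0.52 without KO replicate 2, and the immediate early median was 0.55 without WT replicate 2 and 0.37 without KO replicate 2. With background subtracted, an alternative chosen after seeing the data, the calls of S phase genes (median -0.012, 12 higher and 13 lower, camera adjusted p = 0.437), activation genes (0.0051, 8 higher and 8 lower, 0.907) and immediate early genes (0.33, 0.0851) ended. G2 and M phase genes were then called lower (-0.41, 7 higher and 21 lower, 0.000191; adjusted p = 0.677 with an estimated correlation). WT replicate 2 had 13 cells in the progenitor cluster led by Gins2 and Hes5, and whether the changes of these lists come from the mix of clusters was not tested.

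In KO progenitors 5 lists were lower, beside a lower share of background counts. Of 18 quiescence genes 12 were lower, with a median log2 fold change of -0.49 (same-date value -0.57; camera adjusted p = 0.0343; adjusted p = 0.672 with an estimated correlation). Clu (-1.32 ± 0.38) and Gfap (-1.54 ± 0.48) passed when adjusted over the list alone. All 14 myelin genes were lower, with a median of -0.88 (same-date value -1.40; camera adjusted p = 6.87e-07; adjusted p = 0.635 with an estimated correlation). Cnp (-1.29 ± 0.38) and Fa2h (-1.27 ± 0.39) passed when adjusted over that list alone. Homeostatic microglia genes were lower in 11 of 12 cases, with a median of -0.57 (same-date value -0.75; camera adjusted p = 0.00661; adjusted p = 0.635 with an estimated correlation). Synapse genes were lower in 20 of 25 cases, with a median of -0.45 (same-date value -0.25; camera adjusted p = 0.00661; adjusted p = 0.635 with an estimated correlation). Gabra2 stood at -1.47 ± 0.52, while the glutamate receptor gene Grin1 stood at 1.74 ± 0.58, and at -0.35 without KO replicate 2. Calcium handling genes were lower in 20 of 28 cases, with a median of -0.45 (same-date value -0.35; camera adjusted p = 0.0343; adjusted p = 0.635 with an estimated correlation). Itpr2 (-1.53 ± 0.39, edgeR adjusted p = 0.164) passed when adjusted over that list alone. Without KO replicate 1 the calls ended for quiescence (-0.52, adjusted p = 0.140), calcium handling (-0.55, 0.167), myelin genes (-0.44, 0.305) and homeostatic microglia genes (-0.15, 0.660), and the synapse median was -0.81. Leaving out WT replicate 2 they ended for quiescence (-0.19, 0.820), synapse (-0.29, 0.152) and calcium handling (-0.19, 0.152). Without KO replicate 2 the synapse call ended (-0.16, 0.256) and the myelin and homeostatic microglia medians were -1.49 and -0.96, and without WT replicate 1 the homeostatic microglia call ended (-0.43, 0.224). With background subtracted, mostly in WT, quiescence genes in progenitors were called in the opposite direction (median 1.02, 13 higher and 3 lower, camera adjusted p = 0.00034; adjusted p = 0.677 with an estimated correlation). The calls of calcium handling (0.036, 0.5795), synapse (-0.041, 0.309) and homeostatic microglia genes (-0.68, 0.1496) ended, and myelin genes could not be tested, with under 5 measured.

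In KO stem cells or astrocytes 7 lists were lower. All 20 neurogenic transcription factors were lower, with a median log2 fold change of -1.03 (same-date value -1.01; camera adjusted p = 8.27e-10; adjusted p = 0.596 with an estimated correlation). Of them 7 passed when adjusted over the list alone, among them Dlx2 (-1.47 ± 0.37) and Sp8 (-1.64 ± 0.46). All 28 G2 and M phase genes were lower, with a median of -1.11 (same-date value -1.54; camera adjusted p = 9.95e-09; adjusted p = 0.596 with an estimated correlation). Examples were Top2a (-1.26 ± 0.41) and Hmmr (-1.70 ± 0.59). S phase genes were lower in 17 of 23 cases, with a median of -0.32 (same-date value -0.72; camera adjusted p = 0.0328; adjusted p = 0.658 with an estimated correlation). Mcm5 stood at -1.39 ± 0.48. Migration genes were lower in 20 of 27 cases, with a median of -0.54 (same-date value -0.63; camera adjusted p = 0.000222; adjusted p = 0.596 with an estimated correlation). Of them 3 passed when adjusted over the list alone, led by the neuroblast microtubule proteins Dcx (-1.64 ± 0.35) and Tubb3 (-1.28 ± 0.32). Synapse genes were lower in 23 of 25 cases, with a median of -0.46 (same-date value -0.49; camera adjusted p = 0.000251; adjusted p = 0.596 with an estimated correlation). Among the members were the GABA-synthesising enzymes Gad2 (-1.51 ± 0.43) and Gad1 (-1.21 ± 0.39). Myelin genes were lower in 13 of 14 cases, with a median of -0.87 (same-date value -1.42; camera adjusted p = 3.62e-07; adjusted p = 0.596 with an estimated correlation). Of them 2 passed when adjusted over the list alone, led by the oligodendrocyte transcription factor Myrf (-1.63 ± 0.36). All 12 homeostatic microglia genes were lower, with a median of -0.51 (same-date value -0.61; camera adjusted p = 0.00876; adjusted p = 0.636 with an estimated correlation). Selplg stood at -0.88 ± 0.33. None of the members named passed in edgeR (lowest adjusted p = 0.566, for Dcx and Myrf; SE, n = 2 per genotype). The background share of this class was 32.2% and 52.8% in WT against 15.4% and 17.3% in KO.

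Of these calls, those of G2 and M phase, S phase, myelin and homeostatic microglia genes in stem cells or astrocytes ended without KO replicate 1 (medians -0.555, -0.11, -0.41 and -0.18; camera adjusted p = 0.233, 0.977, 0.114 and 0.608), and the synapse median was -1.05. Without WT replicate 2 the S phase call ended (-0.28, adjusted p = 0.333) and the medians of neurogenic transcription factors, G2 and M phase, migration and synapse genes were -0.62, -0.55, -0.25 and -0.31. The synapse call ended without KO replicate 2 (-0.33, 0.152), where the S phase and myelin medians were -0.65 and -1.47, and the homeostatic microglia call ended without WT replicate 1 (-0.44, 0.195). With background subtracted, an alternative chosen after seeing the data, 0 lists were called lower in stem cells or astrocytes, where myelin genes could not be tested, with under 5 measured. S phase genes were called in the opposite direction (median 0.27, 14 higher and 4 lower, camera adjusted p = 0.00526; adjusted p = 0.745 with an estimated correlation). The medians were then 0.0092 for neurogenic transcription factors (6 higher and 6 lower, camera adjusted p = 0.116), 0.71 for G2 and M phase genes (5 higher and 2 lower, 0.0915), 0.058 for migration genes (10 higher and 9 lower, 0.0684), -0.39 for synapse genes (0.0915) and -0.26 for homeostatic microglia genes (0.535).

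On the higher side stood 9 lists in KO stem cells or astrocytes. Complex I subunits were higher in 34 of 35 cases, with a median log2 fold change of 0.61 (same-date value 0.35; camera adjusted p = 4.47e-10; adjusted p = 0.596 with an estimated correlation). All 38 subunits of complexes II to V were higher, with a median of 0.54 (same-date value 0.35; camera adjusted p = 1.09e-09; adjusted p = 0.596 with an estimated correlation). Fatty acid oxidation genes were higher in 16 of 17 cases, with a median of 0.47 (same-date value 0.72; camera adjusted p = 2.35e-05; adjusted p = 0.596 with an estimated correlation). Members included the thiolase Acaa2 (0.92 ± 0.40) and Acads (0.71 ± 0.32). Oxidative stress genes were higher in 18 of 20 cases, with a median of 0.49 (same-date value 0.52; camera adjusted p = 2.35e-05; adjusted p = 0.596 with an estimated correlation). Named members were the metallothionein Mt1 (1.23 ± 0.51) and Nqo1 (0.73 ± 0.32). Glycolysis genes were higher in 15 of 23 cases, with a median of 0.25 (same-date value 0.60; camera adjusted p = 0.0144; adjusted p = 0.636 with an estimated correlation). Ldhb stood at 1.05 ± 0.48. Tricarboxylic acid cycle genes were higher in 16 of 20 cases, with a median of 0.17 (same-date value 0.33; camera adjusted p = 0.0376; adjusted p = 0.658 with an estimated correlation). Idh2 stood at 0.73 ± 0.40. Ribosomal protein genes were higher in 39 of 39 cases, with a median of 0.54 (same-date value 0.20; camera adjusted p = 1.30e-10; adjusted p = 0.596 with an estimated correlation). Interferon response genes were higher in 14 of 17 cases, with a median of 0.66 (same-date value 0.90; camera adjusted p = 0.000436; adjusted p = 0.596 with an estimated correlation). Among the members were Ifitm3 (0.94 ± 0.36) and Xaf1 (0.83 ± 0.32). Quiescence genes were higher in 15 of 18 cases, with a median of 0.32 (same-date value 0.47; camera adjusted p = 0.0277; adjusted p = 0.596 with an estimated correlation). Cd9 stood at 0.79 ± 0.48. Without WT replicate 2 the calls ended for fatty acid oxidation (0.18, adjusted p = 0.0754), glycolysis (0.12, 0.234), the tricarboxylic acid cycle (-0.0002, 0.664), quiescence (0.09, 0.232) and interferon response (0.29, 0.130). They ended without KO replicate 1 for glycolysis (0.18, adjusted p = 0.424), the tricarboxylic acid cycle (0.25, 0.137), quiescence (0.30, 0.1702) and interferon response (0.06, 0.453). Without KO replicate 2 the medians of complex I, complexes II to V and ribosomal proteins were 0.26, 0.23 and 0.15 and that of glycolysis was 0.48. Leaving out KO replicate 1, those of complex I, complexes II to V and ribosomal proteins were 0.92, 0.89 and 0.91. Leaving out WT replicate 1 the medians of fatty acid oxidation, glycolysis and the tricarboxylic acid cycle were 0.84, 0.54 and 0.38. With background subtracted, the calls ended for fatty acid oxidation (0.275, camera adjusted p = 0.0915), glycolysis (0.43, 0.0936), the tricarboxylic acid cycle (0.015, 10 higher and 10 lower, 0.729) and quiescence (0.077, 0.768).

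Single genes did not pass in stem cells or astrocytes: edgeR called 0 of 16687 genes, with 1250 at an unadjusted p under 0.05 (380 higher, 870 lower), and DESeq2 called 3, all lower. The 3 were Calml4 (DESeq2 log2 fold change -3.24 ± 0.66, adjusted p = 0.0118) and the predicted genes Gm45767 (-2.06 ± 0.44, 0.0159) and B020010K11Rik (-1.78 ± 0.41, 0.0440), named after their values were seen. The smallest p in edgeR on the higher side belonged to the ammonium transporter Rhcg (1.40 ± 0.33), Pin4 (1.45 ± 0.36), the growth factor Pgf (1.23 ± 0.32), the paraspeckle RNA Neat1 (1.48 ± 0.39) and Bdh2 (1.24 ± 0.33). Each had an adjusted p of 0.619, with same-date values from 1.02 for Pgf to 1.59 for Rhcg. On the lower side stood Dlx6os1 (-1.69 ± 0.34), whose counts may be shared with the Dlx6 gene on the other strand, Tppp (-1.70 ± 0.36), Dcx, Sox10, a transcription factor of the oligodendrocyte lineage (-2.02 ± 0.45), each with an adjusted p of 0.566, and Fa2h (-1.40 ± 0.32, 0.615). Same-date values ran from -2.54 for Sox10 to -1.61 for Fa2h (SE, n = 2 per genotype). Groups did not overlap for 3312 of 7745 genes of at least 20 CPM (42.8%, average over the 3 groupings 33.3%). Without WT replicate 1 edgeR called 119 genes, Sox10, Dcx, Myrf and Gad2 among them (adjusted p = 0.00127, 0.0370, 0.0423 and 0.0473). Leaving out WT replicate 2 it called 48, and without KO replicate 1 or KO replicate 2 it called 0.

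**Figure D4:**
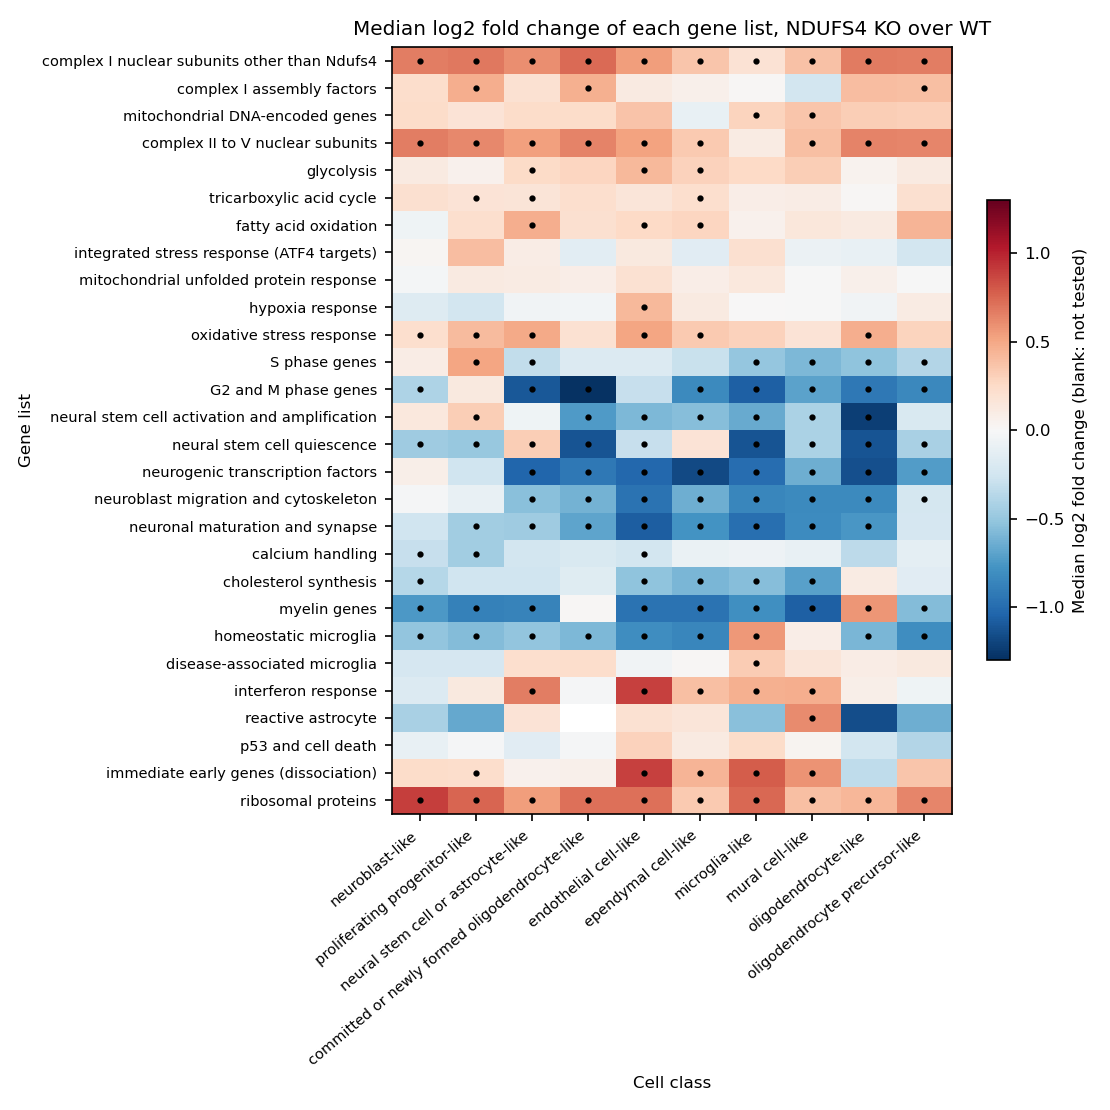
Median log2 fold change (KO over WT) of 28 gene lists, in lines, within each of the 10 tested classes, in columns, with dots where the camera test with its preset correlation had an adjusted p below 0.05. Complex I subunits stood at 0.66, 0.69 and 0.61 in neuroblasts, progenitors and stem cells or astrocytes, and neurogenic transcription factors at 0.08, -0.26 and -1.03.

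Lists that passed in none of the 3 neurogenic classes included the 13 genes encoded in mitochondrial DNA, with median log2 fold changes of 0.24, 0.17 and 0.24 in neuroblasts, progenitors and stem cells or astrocytes (camera adjusted p = 0.120, 0.377 and 0.227). The integrated stress response driven by ATF4 had medians of 0.03, 0.41 and 0.10 (0.285, 0.0868 and 0.230), and the mitochondrial unfolded protein response had medians of -0.02, 0.12 and 0.11 (0.687, 0.147 and 0.161). Hypoxia genes stood at -0.16, -0.24 and -0.05 (0.786, 0.816 and 0.341), and genes of p53 and cell death at -0.10, -0.01 and -0.15 (0.677, 0.862 and 0.533). Reactive astrocyte genes stood at -0.42, -0.67 and 0.18 (0.541, 0.359 and 0.179) and disease-associated microglia genes at -0.22, -0.22 and 0.21 (0.541, 0.614 and 0.112). Neurogenic transcription factors did not pass in neuroblasts (0.08, camera adjusted p = 0.687) or progenitors (-0.26, 0.129), nor did migration genes (-0.02, 0.185, and -0.10, 0.560), and synapse genes did not pass in neuroblasts (-0.26, 0.294). With background subtracted, neurogenic transcription factors were called lower in neuroblasts (-0.37, 0.0134; adjusted p = 0.591 with an estimated correlation) and progenitors (-0.55, 9.56e-05; adjusted p = 0.677 with an estimated correlation), and synapse genes in neuroblasts (-0.39, 0.00114; adjusted p = 0.591 with an estimated correlation). Median, mean and test differed in sign in neuroblasts for migration genes (mean 0.14, test upward) and the mitochondrial unfolded protein response (mean 0.03, test upward). So did activation genes (median 0.14, mean -0.0043), p53 genes (mean 0.0072, test upward) and immediate early genes (median 0.24, mean -0.02). In progenitors the p53 test pointed upward against its median and mean (-0.03), and in stem cells or astrocytes the test pointed upward for hypoxia genes (mean 0.05) and for activation genes (median -0.06, mean -0.02). With an estimated correlation none of the camera calls held in the 3 classes (0 of 10 in neuroblasts, 0 of 14 in progenitors and 0 of 16 in stem cells or astrocytes). Fry, whose directional p asks whether the genes of a list move on balance one way and whose mixed p asks whether they change in either direction, neither in comparison with other genes, called 0 lists by direction (lowest adjusted p = 0.698, 0.505 and 0.528). By its mixed p it called cholesterol synthesis in neuroblasts (0.0154) and activation genes in progenitors (0.0061). Over all tested genes no member of the 28 lists passed in edgeR in these classes, and in neuroblasts 1 immediate early gene, Arc, was lower when adjusted over its list alone.

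The share of mitochondrial transcripts was compared by exact permutation, whose p cannot fall below 0.333 with 2 against 2 libraries, so that it does not show that shares are alike. It was 5.15% ± 0.153 in WT and 5.34% ± 0.682 in KO neuroblasts (SD, n = 2 each; same-date values 5.04% and 4.85%), with an exact permutation p of 1. In progenitors it was 4.20% ± 0.446 and 4.09% ± 0.115 (exact permutation p = 1; same-date values 3.89% and 4.17%). In stem cells or astrocytes it was 4.60% ± 0.117 and 4.81% ± 0.0810 (exact permutation p = 0.333; same-date values 4.51% and 4.75%), with both KO libraries above both WT libraries. Mural cells of the vessel wall had the widest gap of the 10 classes, 4.88% ± 0.0781 against 5.91% ± 0.0171 (exact permutation p = 0.333). In ependymal cells both KO libraries lay below both WT libraries, at 3.72% ± 0.0709 in WT against 3.47% ± 0.0305 in KO (exact permutation p = 0.333). In neuroblasts the difference of 0.19 percentage points turned to -0.29 without KO replicate 2 and was 0.67 without KO replicate 1, and in progenitors the difference of -0.12 points turned to 0.20 without WT replicate 1.

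Among the 7 other classes, genes passed in oligodendrocytes and in mural cells. The share of background was 29.4% and 51.6% in WT against 14.1% and 15.3% in KO oligodendrocytes, and 27.4% and 46.2% against 14.6% and 21.4% in mural cells. In oligodendrocytes edgeR called 30 of 12884 genes, 26 of them lower in KO. Ecrg4 fell by 4.58 ± 0.64 on the log2 scale (adjusted p = 7.00e-05) and Igfbp2 fell by 3.52 ± 0.53 (0.000177). Ttr fell by 6.52 ± 1.00 (adjusted p = 0.000223), Tafa2 fell by 4.54 ± 0.72 (0.000241) and the cilium gene Lrriq1 fell by 4.48 ± 0.76 (0.000922; SE, n = 2 per genotype). Same-date values were -2.49, -2.03, -5.96, -0.53 and -4.70. In mural cells 11 of 9956 genes passed, 8 lower and 3 higher. Ttr fell by 7.22 ± 1.05 (adjusted p = 0.000229), Ecrg4 fell by 3.804 ± 0.76 and Enpp2 fell by 3.05 ± 0.61 (0.0148 each). The near-identical histone genes H2ac23 and H2ac24, whose counts are uncertain, fell by 3.69 ± 0.60 and 3.01 ± 0.55 (adjusted p = 0.00109 and 0.0059). Same-date values were -6.21 for Ttr, -1.73 for Ecrg4, -2.21 for Enpp2, -3.67 for H2ac23 and -3.36 for H2ac24. Genes higher in these classes were named after their values were seen: the haemoglobin genes Hba-a1, Hba-a2 and Hbb-bt in mural cells (4.11, 3.33 and 3.59) and in oligodendrocytes (4.14, 3.63 and 3.27), high in KO replicate 1 alone, and 9330198N18Rik in oligodendrocytes (2.86). DESeq2 called 5 genes in oligodendrocytes (Igfbp2, Chchd10, Calml4 and Gm49394 lower, Grm4 higher, named after their values were seen) and 0 in mural cells, where 561 genes had an unadjusted p under 0.05. Without WT replicate 1 Tafa2 stood at -0.97 (adjusted p = 0.626), Ecrg4 at -2.39 (0.0741) and Ttr at -2.63 (0.0131) in oligodendrocytes, and Ttr at -2.73 (0.220), Ecrg4 at -1.48 (0.9997) and Enpp2 at -1.48 (0.9997) in mural cells. Without WT replicate 2 Lrriq1 stood at -1.05 (1.0) in oligodendrocytes and H2ac24 at -2.35 (0.535) in mural cells. Folds grew to -10.19 and -10.96 for Ttr in oligodendrocytes and mural cells without KO replicate 2, and to -9.77 for H2ac23 in mural cells without KO replicate 1. With 1 library left out, calls in both classes peaked without KO replicate 1. With background subtracted, 15 of the 30 genes in oligodendrocytes and 4 of the 11 in mural cells were left to test and 0 of them passed, with larger SE. Genes lower before stayed lower, at -7.45 to -2.06 in oligodendrocytes and -3.94 to -2.77 in mural cells. Tafa2 in oligodendrocytes then stood at -4.92 ± 1.12 (adjusted p = 0.260), and Hba-a1 stood at 1.27 ± 1.07 (0.7999) there and at 1.09 ± 1.29 (0.9998) in mural cells.

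In the 5 classes left, edgeR called 0 genes each. Microglia, whose cells lay mostly in another cluster in KO replicate 2, with 1524 genes at an unadjusted p under 0.05 and 19 called by DESeq2, showed the stress-induced Osgin1 at 2.01 ± 0.40 and the mitochondrial protein gene Chchd10 at -1.83 ± 0.34 (edgeR adjusted p = 0.292 each; same-date values 2.11 and -1.90). The stress cytokine Gdf15 stood at 1.96 ± 0.46 and Ftl1 at 2.15 ± 0.50 (adjusted p = 0.311 each; same-date values 0.89 and 2.79). Ependymal cells (1028 at an unadjusted p under 0.05, and 2 by DESeq2, Nfasc and Zic4) held Zic4 at -2.42 ± 0.37 and Nfasc at -2.09 ± 0.35 (edgeR adjusted p = 0.402 each; same-date values -2.78 and -2.23). Endothelial cells (1251, and 6 by DESeq2) held elastin, Eln, at -3.10 ± 0.48 (0.291; same-date value -2.59) and the near-identical heat shock genes Hspa1a and Hspa1b, uncertain for that reason, at 2.54 ± 0.50 and 1.84 ± 0.46 (0.309 each; same-date values 2.09 and 2.67). Oligodendrocyte precursors (848, and 2 by DESeq2, Ecrg4 and Cfap57) held the cilium gene Cfap57 at 2.15 ± 0.37 (0.326; same-date value 2.18). Newly formed oligodendrocytes (834, and 3 by DESeq2, Ptcra, Igfbp2 and 4933439K11Rik) held Ptcra at 3.36 ± 0.50 (0.0548; same-date value 2.45). Genes called by DESeq2 in counts of 5 or fewer were named after their values were seen. Chchd10 held 641 and 329 CPM in cell-free barcodes of WT against 232 and 202 in KO. The share of background was 25.3% and 46.4% in WT against 12.9% and 15.6% in KO microglia. In ependymal cells it was 26.8% and 52.5% against 13.7% and 15.1%. Nfasc was also lower in microglia (-1.65) and progenitors (-1.69) in edgeR. Whether background makes the fall of Nfasc was not tested. With 1 library left out, calls peaked without WT replicate 1 in endothelial cells and precursors. They peaked without KO replicate 1 in microglia, ependymal cells and newly formed oligodendrocytes. Without KO replicate 2 Osgin1 and Chchd10 passed in microglia (edgeR adjusted p = 0.00119 and 0.0183), Zic4 and Nfasc in ependymal cells (0.00532 and 0.0362). So did Eln, Hspa1a and Hspa1b in endothelial cells (0.000858, 0.00123 and 0.0118) and Cfap57 in precursors (0.00237). Without KO replicate 1 Gdf15, Chchd10, Zic4 and Nfasc passed (0.000179, 0.0425, 0.0372 and 0.0250), without WT replicate 1 Ftl1 and Eln passed (0.0239 and 0.0347), and without WT replicate 2 Eln passed (0.00689). In newly formed oligodendrocytes Ptcra passed without WT replicate 1, KO replicate 1 or KO replicate 2 (edgeR adjusted p = 0.0399, 2.70e-06 and 0.000866).

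Of the 28 lists, complex I subunits and ribosomal proteins were called higher by camera in all 10 classes and complexes II to V in 9. Neurogenic transcription factors, G2 and M phase, migration, synapse and quiescence genes were called lower in 8. Myelin genes were called lower in 8 classes and higher in oligodendrocytes, the cells that make myelin, where their median was 0.58. Homeostatic microglia genes were likewise called lower in 8 classes and higher in microglia, with a median of 0.57 and a share of background of 25.3% and 46.4% in WT against 12.9% and 15.6% in KO. Interferon response and immediate early genes were each called higher in 5 classes. With an estimated correlation 0 of these calls held in any of the 10 classes, and the lowest adjusted p was 0.546, in endothelial cells.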

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

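Chosen only after the result was seen were the 3 tests of the genes called in progenitors, the comparison of stem cell or astrocyte genes with microglia, and the tests of KO replicate 2 and of complex I alone for the respiratory chain, while the level test of the stem cell or astrocyte genes and the matched sets of the respiratory chain were written beforehand.

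KO replicate 1 held shares of classes outside the tested ones above the level of both WT libraries. Erythrocytes made up 3.20% of its cells (exact 95% binomial interval 2.89 to 3.52, counting error only), against 0.0079% in the higher WT library. Striatal projection neurons made up 1.82% (1.59 to 2.07) against 0.720%, and border macrophages 0.641% (0.508 to 0.798) against 0.499%. In KO replicate 2 these shares were 0.0559%, 0.3635% and 0.2237%. Haemoglobin Hbb-bs reached 14679 CPM in cell-free barcodes of KO replicate 1, against 141, 570 and 591 CPM in WT replicate 1, WT replicate 2 and KO replicate 2.

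The genes that fell in KO progenitors, such as Ecrg4, Enpp2 and Igfbp2, are abundant in choroid plexus, and Tppp in oligodendrocytes. A change within progenitors alone would leave microglia unmoved, but the median difference between the progenitor and microglia log2 fold changes was -0.16 over the 7 of 8 genes measured in both. Choroid plexus tissue in WT replicate 1 alone would end the pattern without that library, where the median of the same 7 was -2.10. For Tafa2 (-0.97), Ecrg4 (-1.17) and Enpp2 (-1.21) most of the fold was then lost. Igfbp2 (-2.23), Tppp (-2.26), Calml4 (-2.71) and Gm49394 (-2.10) kept most of theirs, and Sostdc1 was not measured. That test thus leaves WT replicate 1 open as the main source for Tafa2, Ecrg4 and Enpp2. Free RNA from lysed cells may account for most of the pattern, since these 7 genes had a median of -3.09 in microglia. Tppp stood at -0.40 there, but its level in progenitors did not exceed that of background. It was 33.5 and 35.9 CPM in WT and 7.75 and 6.65 CPM in KO progenitors. Background alone would give 35.6 and 39.4 CPM against 9.88 and 11.1 CPM. Tafa2 in WT replicate 1 stood at 183.6 CPM, above the 43.04 CPM that background alone would give, so that free RNA as estimated here leaves part of it open. A difference between the genotypes in which cells lysed or in choroid plexus or myelin itself stays open and was not tested.

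Neurogenic transcription factors and G2 and M phase genes, 48 in all, had a median of -1.07 in KO stem cells or astrocytes. A change within these cells would put the genes, in WT, above the level that background alone gives, but the highest WT ratio to unrelated markers was 1.01 (WT replicate 1 at 0.895 and WT replicate 2 at 1.01, against 1.31 and 1.45 in the KO libraries). Free RNA may account for the pattern, since the same genes had a median of -1.03 in microglia and the difference between the classes was -0.02 (quartiles -0.33 and 0.32). A change of stem cell commitment with the genotype that is smaller than this spread stays open.

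Nuclear subunits of the respiratory chain, 73 genes, were higher in the 3 neurogenic classes, with a mean of the class medians of 0.63. A response of complex I subunits alone is argued against by complexes II to V, from which complex I differed by 0.045 on average. Short gene length and high abundance may account for most of the shift, since random sets matched for them had a mean of 0.556. The subunit medians lay within the 95% range of these sets in neuroblasts (0.66, upper bound 0.69) and progenitors (0.65, upper bound 0.65). In stem cells or astrocytes they lay above it (0.58, upper bound 0.57). Ribosomal protein genes, 39 of 39 higher in neuroblasts, were not kept out of the sets. The sets therefore cannot tell length and abundance apart from a shift of such genes. Whether KO replicate 2 alone makes the shift cannot be told apart from a genotype effect, since the mean was 0.28 without it and 1 KO library then remains. A mitochondrial response beyond the matched sets stays open as a hypothesis.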

How the results depend on the processing

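Alternatives were chosen before the data were examined, except background subtraction, the clustering of each library on its own and the alternatives of the 7 other classes, which were chosen after seeing the data. Unless stated, the cause was not tested.

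DESeq2's Wald test called 4 genes in neuroblasts, 3 in stem cells or astrocytes, 3 in newly formed oligodendrocytes, 6 in endothelial cells, 2 in ependymal cells, 19 in microglia, 0 in mural cells, 5 in oligodendrocytes and 2 in oligodendrocyte precursors. DESeq2's size factors in edgeR called 0 in progenitors. With no filter on low counts edgeR called 97 genes in neuroblasts, 0 in progenitors and 217 in stem cells or astrocytes. A mean of at least 20 CPM and a mitochondrial limit of 10% each gave 18 in progenitors.

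The labels do not say that replicate numbers pair animals, and deviations of libraries with the same number correlated at 0.004 in neuroblasts, -0.105 in progenitors, -0.0219 in stem cells or astrocytes and -0.138 over all cells. With the replicate number as a replicate block edgeR called 27 genes in neuroblasts, 24 in progenitors, 66 in stem cells or astrocytes, 17 in newly formed oligodendrocytes, 70 in endothelial cells, 70 in ependymal cells, 157 in microglia, 6 in mural cells, 15 in oligodendrocytes and 16 in oligodendrocyte precursors. Called lists came to 7, 14 and 15 in the 3 neurogenic classes. The log2 fold change of the neuroblast share was -0.45, of the progenitor share 0.14, of the stem cell or astrocyte share -0.13, of neuroblasts within the lineage -0.28 and of Ndufs4 -0.25.

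With background subtracted edgeR called 3 genes in neuroblasts, 1 in progenitors, 8 in stem cells or astrocytes, 5 in newly formed oligodendrocytes, 2 in microglia, 0 in mural cells, 6 in oligodendrocytes and 5 in oligodendrocyte precursors. Of the genes called before subtraction only 2 of 8 in progenitors, 4 of 11 in mural cells and 15 of 30 in oligodendrocytes were tested after it, and 0 of them were called, with a larger SE in each. Lower genes stayed lower in mural cells and oligodendrocytes, but Hbb-bt in oligodendrocytes went from 3.27 ± 0.72 to 0.055 ± 1.08. Both WT libraries held at most 1 count after subtraction for 2 of the 3 genes in neuroblasts, all 8 in stem cells or astrocytes and 4 of the 6 in oligodendrocytes. Called lists came to 15 in neuroblasts (12 higher and 3 lower, against 4 and 6 before), 10 in progenitors (8 and 2, against 9 and 5) and 8 in stem cells or astrocytes (8 and 0, against 9 and 7). Directions reversed in neuroblasts for G2 and M phase (0.74, called higher), quiescence (0.19) and cholesterol synthesis genes (0.0502), and in progenitors for S phase (-0.012), quiescence (1.02, called higher) and calcium handling genes (0.036). In stem cells or astrocytes they reversed for S phase (0.27, called higher), G2 and M phase (0.71), neurogenic transcription factor (0.0092) and migration genes (0.058). So did Ecrg4 and Slc7a11 in progenitors (3.67 and 0.053) and Ndufs4 in oligodendrocyte precursors (-0.026). Camera with an estimated correlation called 0 lists in each neurogenic class.

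Without 1 library at a time, with fewer libraries in the test, called genes ranged from 9 to 799 in neuroblasts, 0 to 617 in progenitors, 0 to 119 in stem cells or astrocytes, 24 to 1262 in newly formed oligodendrocytes, 5 to 246 in endothelial cells, 0 to 242 in ependymal cells, 3 to 137 in microglia, 8 to 209 in mural cells, 39 to 263 in oligodendrocytes and 0 to 55 in oligodendrocyte precursors. Called lists ranged from 6 to 11 in neuroblasts and 9 to 18 in stem cells or astrocytes. Ndufs4 ranged from -0.53 to 0.007 over all cells, -0.32 to 0.0005 in neuroblasts, -0.38 to 0.45 in endothelial cells, -0.25 to 0.54 in mural cells and -0.35 to 0.39 in oligodendrocyte precursors. Ndufs5 in neuroblasts ranged from -0.023 to 1.53, Grin1 in progenitors from -0.35 to 2.72 and Gfap in stem cells or astrocytes from -0.15 to 1.16, and the tricarboxylic acid cycle median there from -0.0002 to 0.38. The progenitor share ranged from -0.33 to 0.68 and the stem cell or astrocyte share from -0.37 to 0.13, while the neuroblast share stayed below 0 (-0.91 to -0.03).

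The direction of the progenitor share also reversed with a mitochondrial limit of 10% (-0.33), count minima of 500 (-0.65) and 1000 (-0.13), resolution 2 (-0.0008) and TMM factors (-0.016). In all, shares kept their direction in 55 alternatives and reversed in 9. Named genes stayed on their side of the threshold with the same direction in 1606, passed it in 131, fell short of it in 46 and reversed in 12. Single lists kept their call in 164, lost it in 102 and reversed in 11. Differences of mitochondrial shares without 1 library ranged from -0.29 to 0.67 points in neuroblasts, -0.43 to 0.20 in progenitors and 0.13 to 0.29 in stem cells or astrocytes. Depth limits KO replicate 2 most, with 3576 cells and 851121 counts in neuroblasts.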

Other observations

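Beyond single classes, 53 genes were higher in both KO libraries than in both WT libraries in each of the 10 classes, and 7 were lower, of 4653 genes measured in all of them. Highest were Ftl1, the ferritin light chain (median log2 fold change 1.62), and Pin4 (1.53), and among the others were the ribosomal protein gene Rps2 (1.28) and Gapdh (1.08), which have many near-identical copies and are uncertain. Also among them were Sdhd (0.93), the iron-sulphur cluster scaffold Iscu (0.91), mt-Co1 (0.82) and Ndufb9 (0.79). Lower in every class were Ttr (-6.81), Trim30a (-1.98), Blcap (-1.07), Leng8 (-0.81), Smarcc2 (-0.59) and the predicted genes B020010K11Rik (-1.86) and Gm45767 (-1.74). These genes were named after their values were seen. The other 2 groupings of the libraries gave 28 higher and 11 lower (replicates 2 against replicates 1) and 16 higher and 20 lower (WT replicate 2 and KO replicate 1 against the others), so the 3 groupings are too few to judge chance.

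In microglia, all 12 homeostatic genes were higher in KO, with a median of 0.57 (camera adjusted p = 0.000171; adjusted p = 0.552 with an estimated correlation), beside a share of background of 25.3% and 46.4% in WT against 12.9% and 15.6% in KO. Immediate early genes were higher in 18 of 19 cases (camera adjusted p = 2.94e-10; adjusted p = 0.552 with an estimated correlation). In endothelial cells all 17 interferon response genes were higher (camera adjusted p = 3.67e-07; adjusted p = 0.546 with an estimated correlation). One cluster of microglia marked by Ccl3, Ccl4, Ccl9 and Trem2 held 595 cells, 525 of them from KO replicate 2, or 89.6% of its microglia, and whether the changes in microglia come from this cluster was not tested. DESeq2 called Ccl3 (1.41, adjusted p = 0.0430) and Tnf (1.74, 0.0335) higher in KO microglia, where edgeR gave an adjusted p of 0.3245 and 0.3107. Whether these lists differ between microglia and other classes was not tested.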
